A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

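Cells of the adult human and mouse ocular surface were measured in 6 droplet captures, 3 per species, and each capture gave an mRNA sample and a lectin-tag sample of the same cells, 12 samples in all. The 3 human captures and mouse captures 1 and 2 held cornea with conjunctiva, and the remaining mouse capture held conjunctiva alone. Per the labels' protocols, the tissue compartments were digested apart from each other, the human compartments were pooled afterwards, the cells were fixed in methanol and frozen, and the thawed cells were stained on ice with a mixture of 9 lectins that carry DNA tags. The human captures came from separate donors per the labels. The mouse animals were of strain C57BL/6J, and whether a mouse capture pooled animals was not given in the sources used here.

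The deposited values were counts of unique molecular identifiers (UMIs) per feature and cell, whole numbers that were not normalised, per the labels and the matrices themselves. The submitters' processing notes name Cell Ranger 7.2.0, Seurat without a version, and the builds GRCh38 and mm10. The matrices list 36601 human and 32285 mouse gene features beside the 9 lectins. The submitters' own cell annotation was not used here, and free lectin or free RNA outside cells was not measured here. No genome was used, so gene symbols and identifiers are those the deposited matrices pair, and no coordinates are given.

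Cells with under 300 detected genes or over 20% mitochondrial UMIs were left out, 340 cells in all. Doublets were scored per capture with Scrublet (in scanpy 1.11.5). Its own threshold marked only 15 cells, so the highest-scoring cells were removed at a rate set in proportion to the cells captured, from 1.79% to 9.76% of a capture and 3244 cells in all. Each species was clustered in Seurat 5.3.0 after reciprocal principal component integration of its captures, on 2000 variable genes, 30 dimensions and a resolution of 0.6. The 18 glycan gene lists that the comparisons use, with 221 human and 212 mouse genes in the matrices, were kept out of the clustering. A cluster was called "X-like" from fixed marker genes where at least 3 of that class's markers were detected in at least 10% of its cells, their mean z-score was at least 0.5, no other class had more markers among its 10 leading genes, and its cells' median UMI count lay within a factor of 3 of that of their captures. Where scores lay within 0.5 of the best, the class with most markers among the leading genes was taken. These scoring limits were set after the data were seen, and the classes are rebuilt from markers. 3 clusters in each species stayed unnamed. Vascular and lymphatic endothelial markers were scored as 1 class. The mouse cluster whose leading gene is Car3 passed as a pericyte or smooth muscle class in the scoring, with 1 marker of that class among its 10 leading genes. Car3 is the mouse gene of CA3, a corneal endothelial marker in the fixed list, but its symbol was not matched in the mouse scoring. The cluster is named by its leading gene here.

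Cells are not replicates. UMIs were summed per capture and class where a class had at least 20 cells in at least 2 captures. The lectin sums were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3, limma 3.58.1), with the capture as a block and 1 spread shared by all classes of a species. The share fit took all lectin UMIs of a sum as its size, and the amount fit took its number of cells. A class was set against the unweighted mean of the other classes, giving 72 tests over 8 human classes and 63 over 7 mouse classes, with Benjamini-Hochberg adjustment over each set. Pairs of classes were contrasts in the same fits, adjusted over the 9 lectins. The difference between species was an interaction in 1 fit over 35 sums of 6 captures, with 54 tests over 6 classes. RNA sums were fitted the same way with TMM scaling and edgeR's own filter on low counts, over 13989 human and 12956 mouse genes, and adjusted over all of these. Also given are counts adjusted over all list genes together ("over the list genes alone") and counts adjusted within each single list, which are separate adjustments. Share fits had a common dispersion of 0.0854 (human, 13 residual degrees of freedom) and 0.0596 (mouse, 10), and RNA fits 0.0401 and 0.0717. All adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named, and a call is an adjusted p below 0.05. Levels are shares of all lectin UMIs of a class, lectin UMIs per cell, or CPM, as means ± SD over captures. CPM relate an RNA UMI count to the UMIs of the sum in the genes tested, scaled by TMM.

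The block follows from the design, since the classes of a capture come from the same preparation. It was checked on the lectin shares: the deviations of conjunctival-like and corneal-like sums of the same capture from their class means correlated at 0.591, 0.733 and 0.626 in human captures 1 to 3, and at 0.888, 0.810 and 0.668 in mouse captures 1 and 2 and the conjunctiva-only capture.

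The tests, the marker genes, the gene lists, the lectin and gene pairs and most alternatives were fixed before the data were examined. That plan expected mouse corneal-like sums only from the captures that held cornea. The main fits depart from it by also keeping the corneal-like sum of the conjunctiva-only capture. Genes are named by a fixed rule: among the list genes, the 12 largest rises and the 12 largest falls that passed the test, moved the same way in every capture that held both classes and reached a mean of 10 CPM in a class; MUC1, MUC4, MUC16, MUC5AC, ST6GAL1, C1GALT1 and the genes paired with lectins are given whatever they show; and each class has its 3 largest rises. For correlations across classes, 9 lectin and gene pairs per species were tested by exact permutation. Their p-values were adjusted over all 18 pairs in the main setting, and over the 9 pairs of 1 species in each alternative. The lists were membrane mucins, secreted mucins, O-GalNAc initiation, O-glycan core extension, alpha2,3-sialyltransferases, alpha2,6-sialyltransferases, alpha2,8-sialyltransferases, sialic acid supply, fucosylation, N-glycan trimming and branching, oligosaccharyltransferase, N-acetyllactosamine synthesis, galectins, cell-surface proteoglycans and hyaluronan, heparan and chondroitin sulfate synthesis, keratan and glycan sulfation, glycosphingolipid synthesis and lysosomal glycosidases. Mouse St6galnac2 stands under 2 identifiers in the matrices and is uncertain, and LGALS7 and LGALS7B are near-identical copies whose counts are uncertain.

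Alternatives were run 1 at a time: no capture block, lectin UMIs of each cell capped at the 99th percentile, limma on centred log ratios per cell (which changes the test, the transformation and the weight of each cell together), sums of at least 50 cells, each capture left out, DESeq2 1.42.0 (which changes the test and the scaling together), library totals without TMM, no filter beyond 1 count, a resolution of 1.2, no integration, doublets kept, and stricter cell filters (500 genes, 10% mitochondrial UMIs). 5 kinds were added after seeing the data: AAL left out of the lectin total, RNA UMIs in place of cells as the size of the amount fit, the corneal-like sum of the conjunctiva-only capture left out, all alternatives of the goblet-like comparisons, and fits without the block of amounts between 2 classes, species differences of 1 contrast, corneal-like clusters and leading genes of each class.

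The fits were tested on simulated sums with known answers, drawn from the measured means, sizes and spreads. With no class difference, 5.26% of the human and 4.92% of the mouse lectin tests had an unadjusted p below 0.05, and 6 and 2 of 100 simulations gave a call; for the interaction these were 5.69% and 14 of 100. A single 2-fold change in the share of 1 lectin other than AAL in 1 class was called in 36% of human and 56% of mouse simulations. These calls were adjusted over all 72 human or 63 mouse tests, and contrasts of 2 classes were not simulated for lectins. The median log2 difference was 0.86 and 0.88. A change of AAL was not simulated. For the genes of conjunctival-like against corneal-like cells, over 13989 human genes, 6.87%, 49.0% and 87.3% of changes of 1.5, 2 and 4 times were called, and over 12956 mouse genes 0.597%, 10.7% and 66.7%. In these simulations, which changed few genes, 21.1% of the human and 10.1% of the mouse calls were genes left unchanged, more than the adjusted threshold sets.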

Results

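The series mapped the glycocalyx, the coat of sugar chains on the cell surface, on the surface of the eye in human and mouse adults with 9 lectins, sugar-binding proteins whose DNA tags are counted in the same droplets as the mRNA. MPA and PNA bind the galactose-GalNAc core of mucin-type O-glycans, and PNA prefers that core without sialic acid. ECA and DSA bind N-acetyllactosamine, AAL binds fucose, SNA-I binds alpha2,6-linked sialic acid, MAA-I binds galactose-ended chains that carry sialic acid or sulfate, ConA binds mannose-rich N-glycans, and WGA binds N-acetylglucosamine and sialic acid. 3 human captures and 2 mouse captures held cornea with conjunctiva, and 1 mouse capture held conjunctiva alone.

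The human captures 1 to 3 held 7495, 6930 and 12203 cells, mouse captures 1 and 2 held 2233 and 6904, and the conjunctiva-only mouse capture held 9996. After filters and removal of doublets 42179 of 45761 cells stayed, 24305 human and 17874 mouse. RNA totals were 138186142, 54474828 and 96097197 UMIs in the human captures and 22773851, 62697445 and 73270414 in the mouse captures, in that order. Lectin totals were 29961865, 67660864 and 67841553 UMIs in the human captures and 22828021, 55762071 and 78961978 in the mouse captures. The median cell held 13405, 6467 and 6731 RNA UMIs in human captures 1 to 3, and 6329, 6200 and 4128 in the mouse captures. Its median lectin count was 2353, 5885 and 4569 in the human captures, and 4177, 4611 and 3691 in the mouse captures. The edgeR tests below rest on the spread of class values left between captures once the block has removed each capture's own level. They do not rest on counting error alone.

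AAL took the largest part of the lectin UMIs in the human captures, 59.5%, 69.5% and 45.9%, against 26.3%, 32.0% and 26.6% in the mouse captures. SNA-I took 16.3%, 8.97% and 21.9% in human, second to AAL in each capture, and 23.7%, 27.2% and 37.4% in mouse, where it stood above AAL in the conjunctiva-only capture and below AAL and ConA in mouse capture 1. ConA stood at 6.88%, 6.15% and 8.06% in human and 25.8%, 11.1% and 11.9% in mouse, and DSA at 7.19%, 6.47% and 6.78% against 8.03%, 12.5% and 9.68%. WGA held 3.39%, 3.82% and 8.43% in human and 0.971%, 1.42% and 1.07% in mouse. ECA, MPA, PNA and MAA-I made up the remainder, with at most 9.78% in any capture. The species also differ in dissociation and capture, so these levels were not tested against each other.

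Conjunctival-like epithelium was the largest human class, 58.9% ± 9.47 of cells (SD, n = 3), ahead of corneal-like epithelium with 20.1% ± 7.22 and limbal/basal-like cells with 6.2% ± 1.75. Cycling-like cells made up 1.11% ± 0.909, melanocyte-like cells 0.629% ± 0.258, goblet-like cells 0.571% ± 0.764, stromal-like cells 0.498% ± 0.126 and endothelial-like cells 0.356% ± 0.0100. In mouse, corneal-like cells held 24.5% ± 23.6, conjunctival-like cells 19.7% ± 13.3, limbal/basal-like cells 19.5% ± 18, stromal-like cells 9.72% ± 4.81 and cycling-like cells 7.99% ± 3.68 (SD, n = 3). Mouse goblet-like cells made up 1.14% ± 1.42, myeloid-like cells 0.863% ± 0.857, endothelial-like cells 0.691% ± 0.519 and a cluster led by Car3 0.596% ± 0.216. Unnamed clusters held 11.6% ± 0.166 of human and 15.3% ± 7.29 of mouse cells. With doublets kept, corneal-like cells stood at 11.7% and limbal/basal-like cells at 16.2% in human, and finer clusters put limbal/basal-like cells at 9.65% and unnamed clusters at 20.1%. These shares also follow the dissociation and pooling of the tissues.

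In the conjunctiva-only mouse capture, conjunctival-like cells made up 30.0% and corneal-like cells 2.16%, against 24.3% and 22.2% in mouse capture 1 and 4.72% and 49.3% in mouse capture 2. Limbal/basal-like cells held 39.9%, 12.6% and 5.95% in the same order. The conjunctiva-only capture still held 198 corneal-like cells, which enter the mouse comparisons. The plan had expected corneal-like cells from mouse captures 1 and 2 alone. The 198 cells were kept because they met the fixed minimum of cells per sum. Different clusters held most of a class in different captures. The conjunctival-like cells of the conjunctiva-only capture were mostly in the Lgi2-led (1201 cells) and Krt4-led (976 cells) clusters, and the Psca-led cluster was the largest in mouse captures 1 and 2 (295 and 117 cells).

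**Figure D1:**
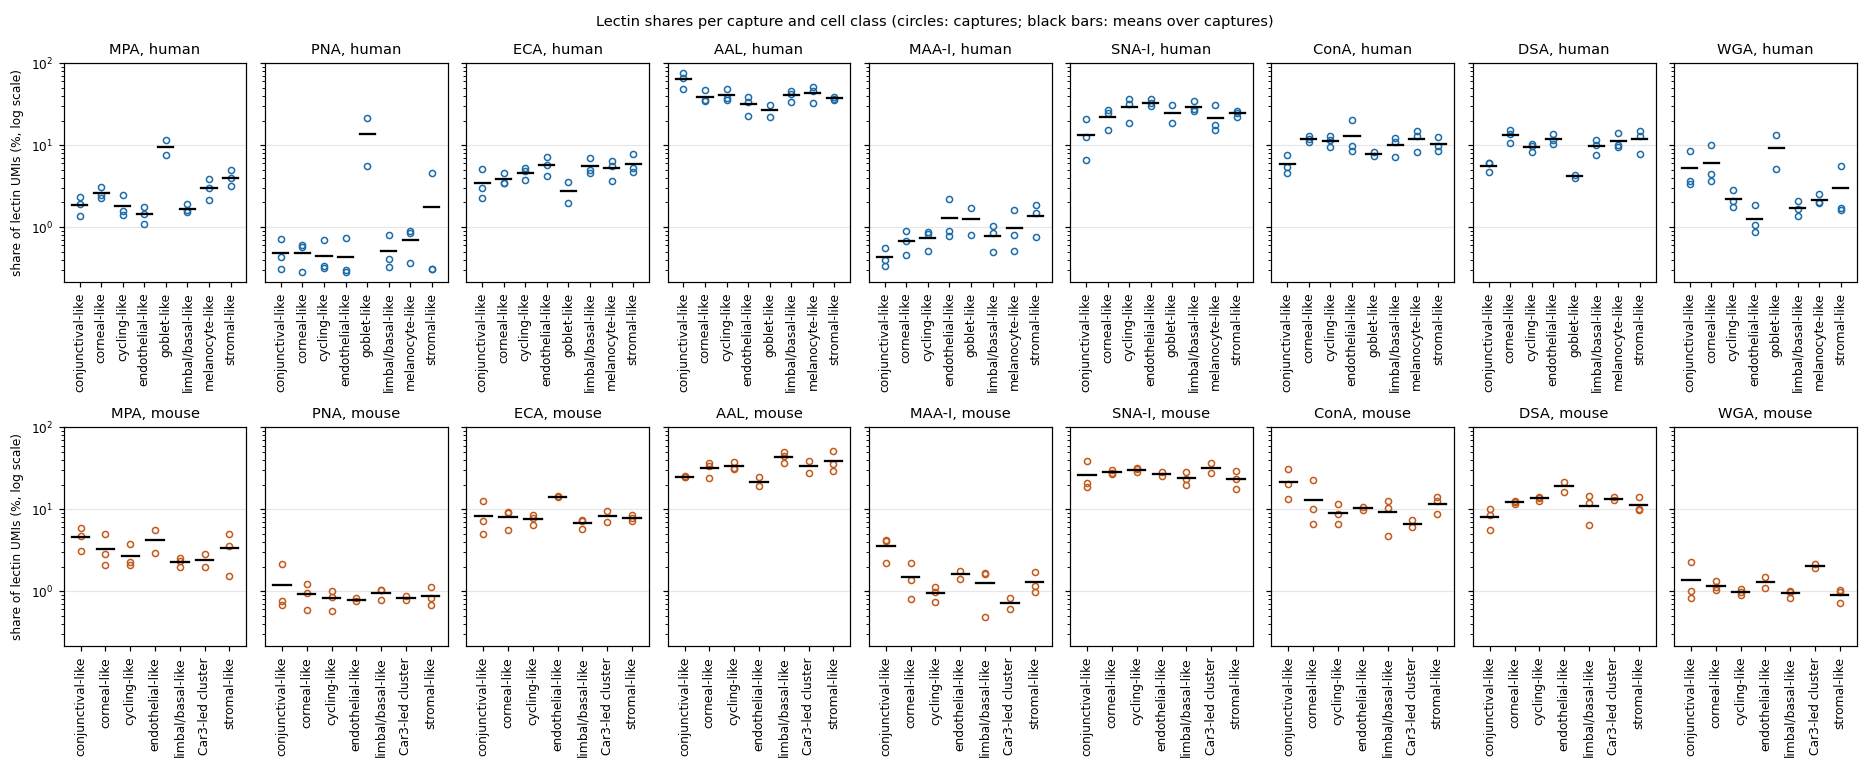
Share of all lectin UMIs (percent, log axis) that each lectin took in each cell class, by species. Circles are captures and bars are means over captures; AAL reached 63.7% on average in human conjunctival-like cells, and PNA 13.6% in human goblet-like cells.

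Human conjunctival-like cells carried relatively more AAL than corneal-like cells, 63.7% ± 14.2 of their lectin UMIs against 39.0% ± 7.09 (SD, n = 3), a log2 difference of 0.71 (SE 0.23, adjusted p = 0.0202). AAL also rose in UMIs per cell, 5144 ± 3956 against 1682 ± 730.3 (log2 1.58, SE 0.34, adjusted p = 0.00186), a call that ended without the block (1.61, adjusted p = 0.176). The shares of DSA, ConA and SNA-I were lower in the conjunctival-like cells. DSA took 5.61% ± 0.792 against 13.2% ± 2.23 (log2 −1.20, SE 0.21, adjusted p = 0.000247), ConA 5.88% ± 1.51 against 11.9% ± 1.03 (−1.01, SE 0.33, adjusted p = 0.0202) and SNA-I 13.4% ± 7.21 against 22.3% ± 6.17 (−0.76, SE 0.28, adjusted p = 0.0340). Each of these 4 lectins moved the same way in 3 of 3 captures. The other 5 lectins did not pass the test: MPA −0.45, PNA −0.08, ECA −0.20, MAA-I −0.57 and WGA −0.22 on the log2 scale, with adjusted p from 0.232 to 0.875. Per cell, no lectin besides AAL passed (DSA −0.47, adjusted p = 0.202, and SNA-I −0.09).

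The calls of DSA, ConA and SNA-I ended when AAL was left out of the total. In that alternative, added after seeing the data, the differences were −0.40 for DSA, −0.23 for ConA and −0.03 for SNA-I, and 0 of the 8 remaining lectins passed by edgeR, with 1 at an unadjusted p below 0.05. Single captures also decided the calls. Without capture 1, 0 of the 9 lectins passed, with 1 at an unadjusted p below 0.05 (AAL 0.58, DSA −1.13, ConA −0.90, SNA-I −0.63), and without capture 2 only DSA did (AAL 0.71 with adjusted p = 0.203, ConA −0.85, SNA-I −0.60). Without capture 3 MPA (−0.73) and MAA-I (−1.10) passed as well. MAA-I also passed with capped cells (−0.88), and WGA turned to 0.67 and passed with limma on centred log ratios. SNA-I lost its call in 5 further settings, between −0.74 without the block and −0.34 with limma.

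Mouse conjunctival-like cells carried relatively more MAA-I and ConA and less DSA than corneal-like cells. MAA-I took 3.51% ± 1.14 against 1.47% ± 0.723 (log2 1.31, SE 0.37, adjusted p = 0.0134), ConA 21.8% ± 9.06 against 13.1% ± 8.41 (0.82, SE 0.30, adjusted p = 0.0435) and DSA 7.99% ± 2.25 against 12.2% ± 0.466 (−0.65, SE 0.25, adjusted p = 0.0435; SD, n = 3). MPA 0.53, PNA 0.29, ECA 0.02, AAL −0.34, SNA-I −0.17 and WGA 0.20 did not pass. The 3 corneal-like sums include that of the conjunctiva-only capture, which the plan had not expected, and no share passed without it. Per cell, all lectins but DSA (0.85, adjusted p = 0.0678) were higher in conjunctival-like cells, led by MAA-I with 702 ± 403 against 104 ± 78.2 UMIs (2.81) and ConA with 4318 ± 2602 against 942 ± 837 UMIs (2.31), and MPA (2.05), PNA (1.93), WGA (1.79), ECA (1.63), SNA-I (1.28) and AAL (1.27) also passed.

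The mouse share calls depended on single captures and on the clustering. None of the 9 lectins passed without the block (MAA-I 1.26), without mouse capture 1 (MAA-I 1.55) or capture 2 (MAA-I 1.09), with finer clusters (0.91), without integration (0.63), with stricter cell filters (0.96) or without the corneal-like sum of the conjunctiva-only capture (0.96). At an unadjusted p below 0.05 edgeR gave 1, 2, 2, 0, 1, 2 and 2 lectins in these settings, in that order. MAA-I alone passed with capped cells, with sums of at least 50 cells and without the conjunctiva-only capture (ConA 0.54, 0.82 and 0.77; DSA −0.49, −0.65 and −0.72). With limma on centred log ratios MAA-I stood at 0.46, ConA (0.21) lost its call, and MPA (0.55) and AAL (−0.39) gained one.

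**Figure D2:**
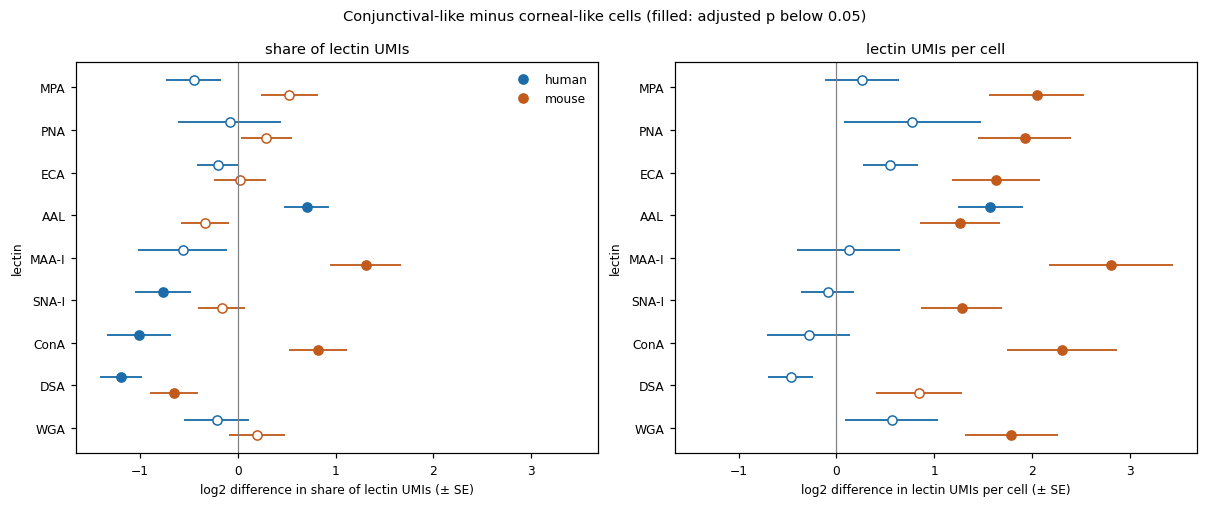
Log2 difference (± SE) between conjunctival-like and corneal-like cells for each lectin, as share of lectin UMIs and as UMIs per cell, in human and mouse. Filled points have an adjusted p below 0.05; AAL stands at 0.71 (share) and 1.58 (per cell) in human.

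Human goblet-like cells, the mucus-secreting cells of the conjunctiva, were set against conjunctival-like cells in captures 1 and 3, which held 101 and 30 of them; capture 2 held 0. PNA took 13.6% ± 11.4 of their lectin UMIs (SD, n = 2) against 0.486% ± 0.214 in conjunctival-like cells (n = 3; log2 4.24, SE 0.63, adjusted p = 1.41e-05). MPA took 9.52% ± 2.72 against 1.85% ± 0.462 (2.41, SE 0.32, adjusted p = 5.94e-06), and MAA-I 1.26% ± 0.648 against 0.430% ± 0.116 (1.41, SE 0.50, adjusted p = 0.0274). The AAL share was lower, 26.7% ± 6.41 (−1.15, SE 0.27, adjusted p = 0.00139). SNA-I 0.75 (adjusted p = 0.0508), WGA 0.68, ConA 0.42, ECA −0.40 and DSA −0.38 did not pass. The SNA-I share was higher in 1 of the 2 captures and lower in 1. Per cell, 8 of 9 lectins passed as higher, with PNA at 2508 ± 2779 against 33.0 ± 11.7 UMIs (log2 5.38), MPA at 1350 ± 313 against 130.0 ± 45.2 (3.69) and SNA-I at 3485 ± 569 against 863 ± 305 (2.08). AAL stood at −0.01 in the fit, although its UMIs per cell were higher in goblet-like cells in 2 of 2 captures. Without the block the amounts of ECA (0.97), ConA (1.55), DSA (0.62) and WGA (2.14) lost their calls and PNA stood at 6.25.

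Set against the mean of all other human classes, 25 of 72 lectin and class pairs passed as shares. Conjunctival-like cells were higher in AAL (log2 0.78, SE 0.16; 63.7% against a mean of 37.0% in the other classes) and WGA (0.80, SE 0.24; 5.19% against 3.65%), and lower in SNA-I (−0.98, SE 0.23), ConA (−0.87, SE 0.26), DSA (−0.77, SE 0.17), MAA-I (−1.11, SE 0.38) and ECA (−0.46, SE 0.17). Corneal-like cells were higher in WGA (1.05, SE 0.23; 6.08% ± 3.55 against 3.52%) and DSA (0.60, SE 0.15; 13.2% against 9.16%). Their WGA share differed between their clusters, 12.6% ± 7.39 in the KRT24-led and 1.98% ± 0.322 in the CXCL14-led cluster (n = 3), and capture 2 held 737 of the CXCL14-led cells against 188 and 176 in captures 1 and 3. Limbal/basal-like cells were lower in WGA (−0.91, SE 0.27; 1.70% ± 0.379 against 4.15%) and MPA (−0.76, SE 0.23).

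Human goblet-like cells stood apart in PNA (log2 4.01, SE 0.38), MPA (2.18, SE 0.22) and WGA (1.57, SE 0.27; 9.14% ± 5.71 against 3.08%, n = 2), and were lower in DSA (−1.20, SE 0.22) and ECA (−0.92, SE 0.21). Endothelial-like cells, in which lymphatic and vascular markers led, were lower in WGA (−1.47, SE 0.29; 1.26% ± 0.533 against 4.21%) and MPA (−1.01, SE 0.24) and higher in SNA-I (0.60, SE 0.20; 33.2% ± 3.57 against 23.5%), DSA (0.44, SE 0.15) and ECA (0.41, SE 0.15). Stromal-like cells were higher in MPA (0.67, SE 0.20; 4.02% against 3.12%), ECA (0.46, SE 0.15) and DSA (0.42, SE 0.15), and cycling-like cells were lower in MPA (−0.66, SE 0.23, lower in 2 of 3 captures). No share of melanocyte-like cells passed. All other pairs named moved 1 way in every capture that held the class.

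As amounts per cell, 26 of 72 human pairs passed. All 9 lectins were higher in goblet-like cells, from log2 0.84 (DSA) to 5.97 (PNA). Conjunctival-like cells were higher in AAL (1.48) and WGA (1.37). Endothelial-like cells were higher in SNA-I (0.58) and DSA (0.45) and lower in MPA (−0.96) and WGA (−1.49). Limbal/basal-like cells were lower in WGA (−1.76), PNA (−1.67), MPA (−1.59), AAL (−0.78) and DSA (−0.72), and melanocyte-like cells in WGA (−1.54), SNA-I (−1.21), AAL (−0.92), MPA (−0.83), ECA (−0.78) and DSA (−0.71). PNA and MPA per goblet-like cell stood at 4.03 and 3.58 with capped cells. Without capture 3 AAL and WGA per conjunctival-like cell reached 2.12 and 2.14, while MPA and WGA per limbal/basal-like cell (−0.97 and −1.10) and WGA per melanocyte-like cell (−0.79) came closer to 0, as did PNA per limbal/basal-like cell with sums of at least 50 cells (−0.67). With limma on centred log ratios, which give no amount per cell, PNA, MPA and WGA stood at 3.11, 1.89 and 1.504 in goblet-like cells, MPA and WGA at −0.61 and −0.76 in limbal/basal-like cells and WGA at −0.75 in melanocyte-like cells. Without the block 6 of the 26 calls held, and 6 passed without capture 1 and 14 without capture 2. With RNA UMIs in place of cells as the size, an alternative added after seeing the data, MPA, ECA, AAL and DSA turned in melanocyte-like cells (0.21, 0.32, 0.22 and 0.40).

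Without the block 15 of the 25 human share calls held, and those of ECA (−0.44) and WGA (0.84) in conjunctival-like, MPA (−0.63) in cycling-like, WGA in limbal/basal-like, ECA (−0.80) in goblet-like, ECA (0.40), SNA-I (0.54) and DSA (0.45) in endothelial-like and ECA (0.45) and DSA (0.46) in stromal-like cells ended. ECA and DSA in endothelial-like and stromal-like cells also lost their calls with each capture left out and with capped cells, with values from 0.19 to 0.52. WGA in conjunctival-like cells reached 1.64 with AAL left out of the total and 1.47 with limma, which put PNA and DSA in goblet-like cells at 3.11 and −1.83. WGA in limbal/basal-like cells stood at −0.15 with doublets kept, and PNA in goblet-like cells at 2.29 with capped cells. Without capture 1, 2 of the 20 pairs still tested held, WGA in corneal-like and MPA in stromal-like cells. Without capture 2, 8 of the 25 held, 5 of them in goblet-like cells, beside DSA and WGA in corneal-like and WGA in endothelial-like cells. With AAL left out of the total, the conjunctival-like values of SNA-I (−0.21), ConA (−0.05) and MAA-I (−0.31) no longer passed, and those of ECA and DSA turned to 0.37 and 0.05. MPA in stromal-like cells turned to −0.04 with stricter cell filters.

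In mouse, 6 of 63 pairs passed as shares. Conjunctival-like cells were higher in MAA-I (log2 1.65, SE 0.26; 3.51% against a mean of 1.21% in the other classes) and ConA (1.15, SE 0.21; 21.8% against 10.0%) and lower in DSA (−0.74, SE 0.20; 7.99% against 13.4%). Endothelial-like cells were higher in ECA (1.00, SE 0.23; 14.2% ± 0.244 against 7.78%, n = 2) and DSA (0.84, SE 0.22; 19.0% ± 3.88 against 11.6%). The Car3-led cluster was higher in WGA (0.87, SE 0.25; 2.04% ± 0.164 against 1.10%, n = 2). All 9 lectins were higher per cell in conjunctival-like cells, from 1.17 (DSA) to 3.62 (MAA-I), and no other of the 63 amounts passed; 14 passed with capped cells, 25 without the conjunctiva-only capture and 25 without integration. Capped cells put MAA-I at 2.69, ConA at 2.35 and PNA at 1.51. MAA-I and PNA stood at 2.89 and 1.65 without mouse capture 2, and WGA at 2.74 without the conjunctiva-only capture. Without integration MAA-I stood at 2.98, ConA at 2.44, PNA at 1.59, WGA at 1.41 and ECA at 1.14, and with limma on centred log ratios MPA at 0.51 and MAA-I and ConA at 0.36.

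The endothelial-like calls and that of the Car3-led cluster ended without the block (ECA 0.87, DSA 0.73, WGA 0.91). DSA in conjunctival-like cells ended without the block (−0.72), without mouse capture 1 (−0.50) and without the conjunctiva-only capture (−0.61), and WGA in the Car3-led cluster ended without mouse capture 1 (0.92). MAA-I and ConA in conjunctival-like cells held in each setting run, with 0.36 for both under limma on centred log ratios. In all, 2 shares passed without the block, 2 without mouse capture 1, 10 without integration and 11 with limma. With RNA UMIs as the size, 4 of the 9 amounts in conjunctival-like cells held, at lower values: MAA-I 2.30, ConA 1.75, MPA 1.18 and PNA 0.94, against 3.62, 3.09, 2.55 and 2.32 per cell. WGA (0.74), ECA (0.46), SNA-I (0.34) and AAL (0.07) no longer passed, and DSA turned to −0.21.

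The difference between the species was tested on the within-capture contrasts, over 6 classes present in both. These classes were matched by markers alone and can differ in make-up. The leading genes of endothelial-like cells included CCL21 and ACKR1 in human, and Ccl21a and Lyve1 in mouse. In the conjunctiva-only capture 2258 of 3657 limbal/basal-like cells were in the Esp6-led cluster, and Esp6 also led in the Lgi2-led conjunctival-like cluster. In conjunctival-like cells, 4 lectins departed from the other classes differently in human and mouse. MAA-I stood at log2 −1.09 in human and 1.54 in mouse (difference −2.62, SE 0.53, adjusted p = 0.000858), ConA at −0.94 and 1.09 (−2.03, SE 0.38, adjusted p = 0.000783), AAL at 0.75 and −0.41 (1.15, SE 0.23, adjusted p = 0.000858) and SNA-I at −1.11 and −0.05 (−1.06, SE 0.27, adjusted p = 0.00635). WGA differed in endothelial-like cells (−1.35 and 0.38; difference −1.73, SE 0.40, adjusted p = 0.00332) and in corneal-like cells (1.29 and 0.08; 1.21, SE 0.37, adjusted p = 0.0240), and MPA in stromal-like cells (1.12 and 0.02; 1.10, SE 0.31, adjusted p = 0.0134). For conjunctival-like minus corneal-like cells, AAL (1.04, SE 0.30, adjusted p = 0.00869), ConA (−1.84, SE 0.48, adjusted p = 0.00643), MAA-I (−1.92, SE 0.65, adjusted p = 0.0212) and MPA (−0.99, SE 0.39, adjusted p = 0.0421) differed between the species, MPA not without the block (−0.96).

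Of the 7 differences by class, those of AAL, MAA-I and ConA in conjunctival-like cells held in every setting that could be run, and these 3 alone passed without the block. With AAL left out of the total MAA-I stood at −1.58 and ConA at −0.99, and with limma on centred log ratios at −1.26 and −0.89. SNA-I fell to −0.08 with AAL left out and lost its call without the block (−1.01), without human capture 1 (−0.97), human capture 2 (−0.80) or the conjunctiva-only capture (−0.73), and with doublets kept (−0.74). WGA in corneal-like cells lost it without the block (1.27), without mouse capture 1 (0.85), the conjunctiva-only capture (0.93) or integration (1.11), and with sums of at least 50 cells (0.82). MPA in stromal-like cells lost it without the block (1.11), without human capture 2 (0.99), mouse capture 1 (1.05) or mouse capture 2 (0.74), and with stricter cell filters (0.43), and WGA in endothelial-like cells only without the block (−1.63). 13 differences passed with capped cells, 16 with limma and 11 without human capture 3.

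Glycan genes, which had been kept out of the clustering, were compared between the same epithelia. Human conjunctival-like cells expressed more of the membrane mucins MUC1 and MUC4, which line the epithelial surface. MUC1 (ENSG00000185499) reached 129 ± 91.4 CPM against 10.5 ± 9.63 in corneal-like cells (SD, n = 3; log2 3.72, SE 0.26, adjusted p = 3.52e-11), and MUC4 (ENSG00000145113) 88.2 ± 20.4 against 8.12 ± 5.45 (3.64, SE 0.34). GCNT3 (ENSG00000140297), which branches O-glycan cores, reached 143 ± 31.1 against 14.5 ± 6.92 CPM (3.37, SE 0.27). MUC22 fell by 4.10 on the log2 scale, 4.56 ± 1.68 against 74.1 ± 21.9 CPM, and MUC16 by 1.05, 57.8 ± 35 against 126 ± 82.2 (adjusted p = 0.0148). Of 179 list genes tested, 44 rose and 33 fell by edgeR's quasi-likelihood test adjusted over all 13989 genes, of which 2167 rose and 1798 fell; adjusted over the list genes alone, 48 rose and 33 fell.

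Of 14 fucosylation genes 6 rose in human conjunctival-like cells and none fell. FUT2, which makes the H antigen of secretions, reached 28.5 ± 7.51 against 6.37 ± 1.37 CPM (log2 2.15), FUT6 5.12 against 0.474 (3.46), FUT3 83.9 ± 38.5 against 44.9 ± 50.8 (1.46) and GMDS, the first enzyme of GDP-fucose synthesis from GDP-mannose, 341 ± 19.9 against 132 ± 19.9 (1.38), and TSTA3 and SLC35C1 completed the 6. FUT1 (0.12), FUT8 (−0.00) and FUT11 (−0.15) did not pass. Among the sialyltransferases the members went both ways. In the alpha2,3 list ST3GAL3 rose (41.7 ± 27.2 against 10.9 ± 3.83 CPM, 1.76) and ST3GAL6 fell by 4.23 (0.824 against 14.9 CPM) with ST3GAL5, and ST3GAL4 stood at 0.63 (adjusted p = 0.0841). In the alpha2,6 list ST6GALNAC1, ST6GALNAC4 (1.89) and ST6GALNAC6 rose, and ST6GALNAC3 (−5.01; 1.05 ± 0.317 against 36.6 ± 13.5 CPM), ST6GALNAC2 and ST6GAL1 (−1.31; 1.84 against 4.88 CPM, lower in 2 of 3 captures, adjusted p = 0.00882) fell.

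O-GalNAc initiation enzymes split evenly, 4 of 15 up and 4 down. GALNT14 rose (log2 2.92; 40.4 ± 10.6 against 5.73 ± 3.57 CPM) with GALNT1, GALNT4 and GALNT5, and GALNT18 (−3.96; 3.92 against 61.6 CPM) and GALNT17 (−1.58) fell with GALNT6 and GALNT11. Core extension had 3 of 7 up (GCNT3, B3GNT3 and C1GALT1, the core synthase, at 0.62 with adjusted p = 0.00605), N-acetyllactosamine synthesis 7 of 16 up and 1 down (B4GALT1 0.76), and N-glycan trimming and branching 4 of 13 up and 1 down (MAN1A1 1.42, MGAT4B 1.16, MAN1A2 0.72 and MGAT2 up, MAN2A1 −0.78 down; MAN1C1 0.11, MGAT4A 0.45 and MGAT5 0.53 did not pass). A4GALT, which makes the globo series, rose (1.88; 346 ± 23.9 against 97.0 ± 19.6 CPM) and ST3GAL5 fell among 5 glycosphingolipid genes. Of 8 membrane mucins 5 rose, with MUC20 (1.58; 221 ± 48.6 against 91.0 ± 61.9 CPM), MUC13 and MUC21 beside MUC1 and MUC4, and MUC7 was the 1 of 2 secreted mucins that rose; MUC5AC stood at −0.56.

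Of 28 heparan and chondroitin sulfate genes 8 fell and none rose, among the falls CHST11 (log2 −3.56; 1.11 against 12.8 CPM) and SULF2 (−1.58; 5.99 against 18.3). Surface proteoglycans and hyaluronan genes had 2 of 21 up (HAS3 and HYAL1) and 4 down, with GPC6 at −3.08 (2.08 against 16.9 CPM). Galectins split 3 up (LGALS3BP, LGALS8 and LGALS9) and 3 down of 7 (LGALS1 −1.87, LGALS7 −1.92 and LGALS7B −1.76, the latter near-identical copies). Of 9 oligosaccharyltransferase genes RPN1 rose and TUSC3 fell (−4.86; 0.335 against 11.7 CPM). Sialic acid supply had 1 up (NANP) and 1 down (SLC35A1) of 5, keratan and glycan sulfation 1 down (CHST2) of 4, lysosomal glycosidases 2 up (FUCA2 and MAN2B1) and 2 down (GLA and MANBA) of 11, and none of 3 alpha2,8-sialyltransferases passed. Adjusted within each single list, the counts became 2 up and 2 down for alpha2,3-sialyltransferases, 4 and 3 for alpha2,6-sialyltransferases, 2 and 1 for sialic acid supply, 5 and 1 for N-glycan genes and 3 and 2 for lysosomal glycosidases, and did not change for the other lists.

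All genes taken as largest rises or falls moved 1 way in 3 of 3 captures. Without the block 19 list genes rose and 21 fell, and MUC20 (1.28), FUT3 (0.90), LGALS7 (−1.47), GALNT17 (−1.38), B4GALT1 (0.79), C1GALT1 (0.57), MAN1A2 (0.72), MAN2A1 (−0.89), MUC16 (−1.13) and ST6GAL1 (−1.39) lost their calls. Without capture 1, 21 rose and 23 fell. Calls also ended without capture 1 for MAN1A1 (1.18), GALNT17 (−1.60), B4GALT1 (0.78), C1GALT1 (0.50), MUC16 (−1.001) and ST6GAL1 (−1.18), without capture 2 for FUT3 (0.77), LGALS7B (−1.16) and C1GALT1 (0.53), and without capture 3 for MAN1A1 (0.93), B4GALT1 (0.57), MAN1A2 (0.58), MAN2A1 (−0.52) and ST6GAL1 (−0.98). DESeq2 did not call GALNT17 (−1.65), LGALS7 (−1.97) or MUC16 (−1.07). With doublets kept LGALS1 (−0.56), LGALS7 (−0.84) and LGALS7B (−0.54) ended and FUT8 stood at 1.07, and stricter cell filters ended LGALS1 (−0.75) and SULF2 (−0.62). Stricter filters moved MAN1A1 to 2.83, TUSC3 to −3.64, CHST11 to −2.66, LGALS7 to −1.21 and LGALS7B to −1.13, finer clusters MAN1A1 to 2.56 and CHST11 to −2.97, and the lack of integration TUSC3 to −3.97. Doublets kept also moved MAN1A1 to 2.98, TUSC3 to −3.31, CHST11 to −2.72, GCNT3 to 2.74, FUT6 to 2.71, SULF2 to −0.66 and MUC16 to −1.67. Left-out captures moved CHST11 to −4.62 and LGALS7 and LGALS7B to −2.73 (capture 1), GPC6 to −2.43 and MAN1A1 to 2.06 (capture 2), and FUT3 to 2.09, GALNT17 to −2.30 and GPC6 to −3.67 (capture 3).

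**Figure D3:**
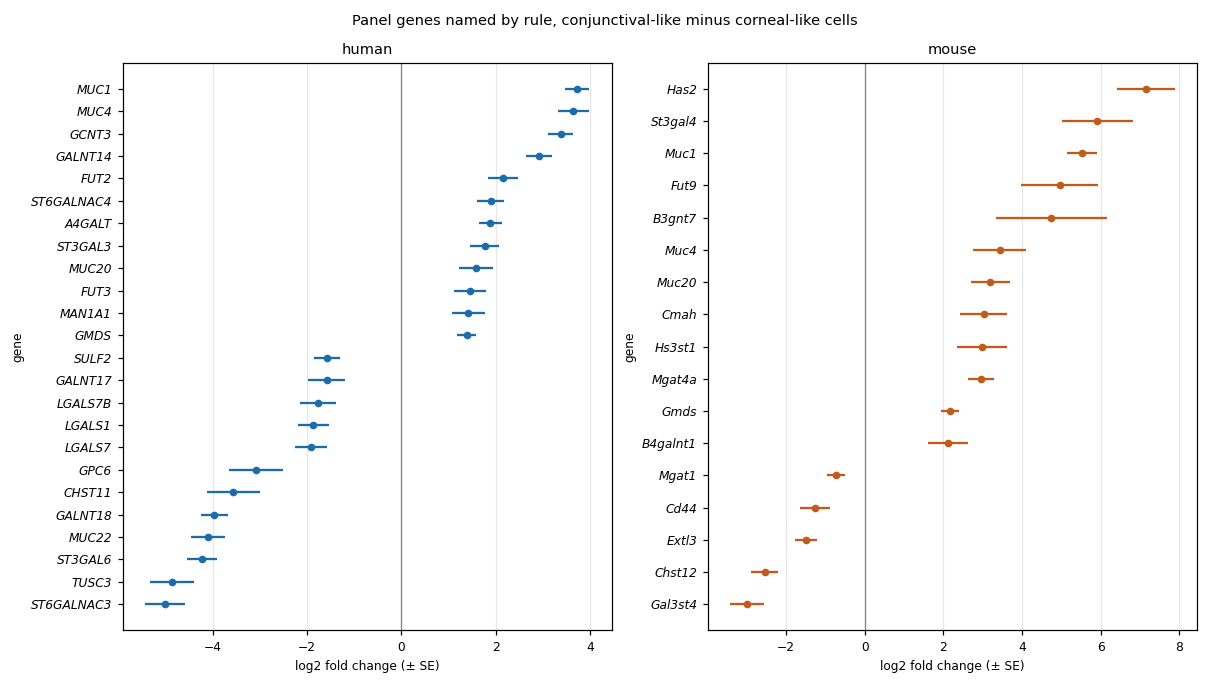
Log2 fold change (± SE) of the named glycan genes between conjunctival-like and corneal-like cells in human and mouse, 3 captures each. Points to the right are higher in conjunctival-like cells; MUC1 stands at 3.72 in human and Muc1 at 5.53 in mouse.

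Mouse conjunctival-like cells also expressed more of the membrane mucins Muc1, Muc4 and Muc20 than corneal-like cells. Muc1 (ENSMUSG00000042784) reached 292 ± 238 against 7.2 ± 5.24 CPM (SD, n = 3; log2 5.53, SE 0.39, adjusted p = 1.76e-06), Muc4 (ENSMUSG00000079620) 1048 ± 496 against 94.9 ± 62.4 (3.43, SE 0.67) and Muc20 179 ± 61.5 against 17.6 ± 5.98 (3.19, SE 0.50). Has2, a hyaluronan synthase, reached 54.9 ± 35.7 CPM in conjunctival-like cells and had only 4 UMIs in corneal-like cells (7.15). St3gal4 (141 ± 76.4 against 7.06 ± 10.6 CPM, 5.91), Fut9 (135 ± 108 against 22.0 ± 38.1, 4.96) and Cmah, which converts CMP-sialic acid to its hydroxylated form (410 ± 196 against 60.1 ± 49.6, 3.03), rose as well. Of 168 list genes tested, 27 rose and 16 fell adjusted over all 12956 genes, of which 1209 rose and 501 fell; adjusted over the list genes alone, 30 rose and 20 fell.

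Of 5 mouse membrane mucins 4 rose, Muc13 being the remaining one, and the 1 secreted mucin tested did not pass (Muc5ac −0.34). All 12 Muc5ac UMIs of corneal-like cells came from the conjunctiva-only capture, so the value rests on that sum. In mouse captures 1 and 2 corneal-like cells had 0 UMIs each, and conjunctival-like cells had 5 and 0. Fucosylation had 4 of 11 up (Fut9, Fut8 with 1.19, Gmds with 2.17 and Slc35c1) and Fut11 at 0.21. Sialic acid supply had 4 of 6 up (Cmah, Cmas, Gne and Slc35a1). The alpha2,3-sialyltransferases had 2 up (St3gal1 and St3gal4) and 2 down (St3gal2 and St3gal5) of 6, with St3gal3 at 0.42 and St3gal6 at −0.14, and none of 6 alpha2,6-sialyltransferases passed (St6gal1 −1.39, adjusted p = 0.157). Galnt3 and Galnt12 rose and Galnt1 fell among 13 initiation enzymes, B3gnt7 (4.75), B3gnt8 and Gcnt2 rose among 16 N-acetyllactosamine genes, and Mgat4a (243 ± 115 against 26.2 ± 6.51 CPM, 2.95) and Mgat3 rose and Mgat1 (−0.73) fell among 12 N-glycan genes. None of 3 core extension genes (C1galt1 1.27, adjusted p = 0.153), 9 oligosaccharyltransferase genes or 7 galectins passed.

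Among 21 surface proteoglycan and hyaluronan genes Has2 and Bgn rose and Cd44 (log2 −1.27; 63.1 ± 6.67 against 150 ± 54.2 CPM) and Gpc1 fell. Of 28 heparan and chondroitin sulfate genes Hs3st1 rose (2.98) and 4 fell, Chst12 (−2.55), Extl3 (−1.49), Chsy1 and Csgalnact1. Gal3st4 (−2.99; 1.93 against 14.2 CPM) and Gal3st1 fell among 7 sulfation genes, B4galnt1 rose (2.12) and A4galt, St3gal5 and Ugcg fell among 5 glycosphingolipid genes, St8sia6 rose and St8sia4 fell among 2 alpha2,8-sialyltransferases, and Fuca2 rose and Gusb fell among 11 lysosomal glycosidases. B4galt1 (0.49), Man1a (−1.59), Man1a2 (−0.04), Man1c1 (2.60), Man2a1 (0.83), Mgat4b (−0.07) and Mgat5 (0.22) did not pass. Adjusted within each single list, the counts became 1 up for core extension, 2 up and 1 down for alpha2,6-sialyltransferases, 5 up for sialic acid supply, 2 and 2 for N-glycan genes and 4 and 2 for N-acetyllactosamine genes, and did not change for the other lists.

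Without mouse capture 1, only 1 list gene rose and 0 fell by edgeR, with 27 and 16 at an unadjusted p below 0.05, and of the genes named above Muc1 alone kept its call (Muc4 3.52, Muc20 3.10, Has2 7.40, St3gal4 4.81, Fut9 4.27, Cmah 2.82, Mgat4a 2.74, Gmds 1.80). Without mouse capture 2 the calls of Fut9 (3.88), B3gnt7 (4.77), B4galnt1 (1.45), Mgat1 (−0.66) and Fut8 (0.97) ended. Library totals without TMM moved the median of all genes from 0.04 to −0.34 and turned the split from 27 up and 16 down to 21 and 26. Without the block 8 rose and 4 fell (Muc4 3.45, Cmah 2.83, Fut9 3.01 and Cd44 −1.26 among those lost), and without integration 11 rose and 13 fell (Muc4 2.07, Muc20 2.35 and Cmah 2.32 among those lost). Finer clusters gave 31 up and 27 down, stricter cell filters 30 and 25, and doublets kept 43 and 37. With doublets kept Hs3st1 (0.76), Mgat1 (−0.68) and Fut8 (0.65) ended, and Mgat5 turned to −1.43. Doublets kept also moved Has2 to 4.24, St3gal4 to 4.50, Muc1 to 6.92, Muc4 to 5.09, Muc20 to 5.33, B3gnt7 to 5.82, B4galnt1 to 3.31, Gmds to 2.997, Gal3st4 to −4.54 and Cd44 to −2.92. Finer clusters moved Has2 to 4.66, St3gal4 to 4.58, Fut9 to 4.05 and Gal3st4 to −3.65, stricter filters Has2 to 4.80, St3gal4 to 4.52, Fut9 to 4.02 and Hs3st1 to 2.38, and the lack of integration Has2 and B3gnt7 to 5.72, Fut9 to 7.60 and Mgat4a to 1.87. Without the conjunctiva-only capture Fut9 stood at 8.85, St3gal4 at 7.05 and B4galnt1 at 2.82, without its corneal-like sum Fut9 at 8.49 and St3gal4 at 6.997, without mouse capture 1 Muc1 at 4.85, and without mouse capture 2 St3gal4 at 5.06 and Gal3st4 at −3.65. Has2 stood at 8.25 and St3gal4 at 5.30 without the block, and St3gal4 at 4.97 with DESeq2.

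Human goblet-like cells expressed far more MUC5AC (ENSG00000215182), the gel-forming mucin of the tear film, than conjunctival-like cells, 3123 ± 2082 CPM (SD, n = 2) against 9.09 ± 15 (n = 3; log2 9.01, SE 1.05). B3GNT6, an enzyme of the O-glycan core extension list, reached 17.4 ± 8.92 CPM and had 4 UMIs in conjunctival-like cells (8.73). The initiation enzymes GALNT10 (4.24; 31.7 against 1.57 CPM), GALNT6 (3.81), GALNT17 (3.59; 62.6 against 4.29 CPM) and GALNT18 (2.69) rose, 4 of 15 with none down. FUT8, which adds core fucose to N-glycans (3.47; 27.4 ± 4.37 against 2.24 CPM), ST6GAL1, which adds alpha2,6-linked sialic acid (3.05; 16.5 ± 7.60 against 1.84 CPM), and GPC4 (5.16; 17.7 against 0.489 CPM) rose as well. MUC21 (−1.77; 139 against 370.5 CPM), C1GALT1C1 (−1.31), the chaperone of the core synthase C1GALT1, and LGALS3 (−1.18) fell. Of 179 list genes 31 rose and 11 fell, and 36 and 13 adjusted over the list genes alone.

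Of 8 membrane mucins MUC16 rose (log2 1.66; 244 against 57.8 CPM), MUC15 (−1.23) and MUC21 fell, and MUC1 (−0.17) and MUC4 (0.67) did not pass. MUC5AC was the 1 of 2 secreted mucins that rose, and B3GNT6 and GCNT1 (3.33) rose and C1GALT1C1 fell among 7 core extension genes, with C1GALT1 at −0.50 (adjusted p = 0.103). N-glycan genes had 5 of 13 up, MAN1C1 (3.63), MAN1A1 (1.89), MGAT4A (1.66), MGAT5 (1.58; 213 against 69.6 CPM) and MAN2A1 (1.41), and MGAT4B (−0.97) down. FUT6 (2.08), FUT8 and GMDS rose among 14 fucosylation genes, and FUT1, FUT2, FUT3 and FUT11 lay between −0.48 and 0.21. None of 6 alpha2,3-sialyltransferases passed (ST3GAL3 −0.76, ST3GAL4 −0.64, ST3GAL6 1.55), ST6GAL1 rose and ST6GALNAC6 (−0.96) fell among 7 of the alpha2,6 list, ST8SIA6 rose among 3 of the alpha2,8 list, and none of 5 sialic acid supply genes passed. Heparan and chondroitin sulfate genes had 7 of 28 up, SULF2 (2.73) among them, and HS3ST1 (−1.05) down, and GPC4 and VCAN rose among 21 proteoglycan and hyaluronan genes. B4GALNT3 and GCNT2 rose and B3GNT8 (−0.98) and B4GALT3 (−0.93) fell among 16 N-acetyllactosamine genes (B4GALT1 0.33), UGCG rose and A4GALT (−0.98) fell among 5 glycosphingolipid genes, CHST9 rose among 4 sulfation genes, DAD1 (−0.82) fell among 9 oligosaccharyltransferase genes, LGALS3 fell among 7 galectins, and none of 11 lysosomal glycosidases passed. MAN1A2 stood at 0.70 (adjusted p = 0.0555).

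All alternatives of the goblet-like comparisons were chosen after seeing the data. Where a capture left a lone goblet-like sum, that sum was assumed to vary like the other classes. As shares, MPA, PNA and AAL passed in each setting run, but PNA stood at 2.40 with capped cells and 2.98 with limma on centred log ratios, MPA at 1.46 and PNA at 3.15 with AAL left out of the total, and MPA at 1.80, MAA-I at 0.44 and AAL at −2.04 with limma. MAA-I lost its call without capture 1 (0.94), without capture 2 (1.23) and with AAL left out (0.49), and reached 2.09 without capture 3. SNA-I passed without capture 3 (1.45), with capped cells (0.92), with finer clusters (0.79), without integration (0.77) and with doublets kept (0.73). ConA (0.58) and WGA (0.84) passed with capped cells, ConA turned to −0.50 with limma, and ECA and DSA passed with AAL left out (−1.39 and −1.36) and with limma (−1.26 and −1.32).

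The goblet-like gene counts rested on capture 1, without which 3 list genes rose and 0 fell by edgeR, with 19 and 3 at an unadjusted p below 0.05. Of the 24 named genes still tested there, MUC5AC (10.99) and FUT8 (3.71) held, and ST6GAL1 (2.54), MUC16 (1.19), GALNT17 (3.17), GALNT18 (1.07), MGAT5 (1.28) and SULF2 (2.32) were among those lost. The number of falls moved with the scaling alone, with test and scaling together (DESeq2), and with the count filter. Against a median of all genes of −0.19, library totals without TMM put it at 0.19 and gave 44 up and 3 down, DESeq2 put it at 0.05 and gave 37 and 7, and testing all 29836 genes put it at −0.71 and gave 31 and 29. Without the block 24 rose and 0 fell (11 fell at an unadjusted p below 0.05), and MUC16 (2.08), MAN2A1 (1.31), MUC21 (−1.45), C1GALT1C1 (−1.27) and LGALS3 (−1.16) were among those that ended. DESeq2 did not call MUC16 (1.64), MUC21 (−1.53), FUT6 (2.15) or B3GNT6 (9.66). Without capture 3, 6 fell, FUT6 (1.86), GCNT1 (2.49) and LGALS3 (−1.34) ended, and MUC5AC stood at 7.50, B3GNT6 at 9.34, GALNT6 at 4.50 and GALNT17 at 4.44. MUC5AC stood at 8.41 without the block, 9.61 with DESeq2 and 8.15 without integration, which put GCNT1 at 2.57.

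In the conjunctiva-only mouse capture 251 goblet-like cells gave a sum, against 15 and 0 cells in mouse captures 1 and 2, so no test was made. Muc5ac stood at 1050.4 CPM there (95% exact Poisson interval 1015 to 1086) against 5.42 (4.64 to 6.28) in the conjunctival-like cells of the same capture, and Muc5b at 64.9 (56.4 to 74.3) against 0.712 (0.451 to 1.07). These CPM are relative to all RNA UMIs of the sum, without TMM, and the intervals cover counting error only. Of their lectin UMIs SNA-I took 46.0%, DSA 5.01%, MPA 2.22% and PNA 0.573%, against 38.9%, 8.45%, 3.12% and 0.752% in the conjunctival-like cells of that capture. In the 15 cells of mouse capture 1 ConA took 40.2%, SNA-I 17.8%, MPA 5.08% and PNA 4.54%, against 31.5%, 20.95%, 5.87% and 0.669%.

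The leading glycan genes of each class, some of them shared by 2 classes, were taken against the mean of the other classes on the log2 scale. Human conjunctival-like cells led in GCNT3 (3.70), FUT2 (3.49) and MUC21 (3.06), corneal-like cells in MUC22 (6.13), GPC6 (4.16) and ST6GALNAC3 (2.62), limbal/basal-like cells in GPC3 (6.19), GPC5 (4.41) and the hyaluronan synthase HAS3 (3.62; 48.0 ± 6.61 CPM against a mean of 4.92), goblet-like cells in MUC5AC (9.40), B3GNT6 (8.67) and FUT6 (5.60), and cycling-like cells in MUC22 (2.61), TUSC3 (2.45) and LGALS1 (2.28). Endothelial-like cells led in ST8SIA4 (8.46), CSGALNACT1 (8.03) and VCAN (7.35), melanocyte-like cells in CHST9 (7.34), CHSY3 (7.12; 136 ± 75.1 CPM against 11.1) and ST8SIA6 (6.85), and stromal-like cells in GALNT16 (9.24), VCAN (8.69) and the syndecan SDC2 (8.25; 107 ± 39.2 CPM against 0.971). The reference is a mean of log values, so that MUC22 in cycling-like cells, at 7.71 CPM, lay below the arithmetic mean of the others, 12 CPM, which corneal-like cells raised.

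Mouse conjunctival-like cells led in Muc4 (log2 7.10), Muc1 (6.37) and Muc20 (5.55), corneal-like cells in Hs3st3b1 (3.24), Muc4 (3.10) and Mgat3 (2.98), limbal/basal-like cells in B4galnt1 (3.93), Lgals7 (3.33; 925 ± 196 CPM against 207) and Mgat3 (2.44), and cycling-like cells in B3gnt3 (2.72), St8sia6 (2.15) and Gal3st4 (2.07). Stromal-like cells led in Has1 (9.05; 861 ± 961 CPM against 2.03), Sulf1 (8.03) and the keratan sulfate sulfotransferase Chst5 (7.46), endothelial-like cells in Galnt15 (7.28), St6galnac3 (7.03) and St8sia4 (6.48), and the Car3-led cluster in Cemip (8.12), Gpc6 (6.67) and Bgn (6.29). Muc4 in corneal-like cells and Mgat3 in limbal/basal-like cells stood below the arithmetic mean of the other classes (94.9 against 179 CPM and 25.3 against 27.0 CPM). Without the block St8sia6 (2.26) and Gal3st4 (2.10) in cycling-like and Mgat3 (2.38) in limbal/basal-like cells lost their calls, and Has1 stood at 9.67, Chst5 at 8.19, Galnt15 at 8.14 and Gpc6 at 5.57.

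Lectin shares were compared with the transcripts of enzymes that make their ligands across class means, 9 pairs in each species over 8 human and 7 mouse classes. None of the 18 pairs passed the exact permutation test after Benjamini-Hochberg adjustment, and 1 of 18 had an unadjusted p below 0.05. In that pair, human DSA against the sum of MGAT4A, MGAT4B and MGAT5, which add the branches of N-glycans, the relation was negative (Pearson r −0.73, exact p = 0.0357, adjusted p = 0.643, and Spearman rho −0.67, exact p = 0.0831). Its r was −0.53 without stromal-like and goblet-like cells, and it turned to 0.25 with DSA UMIs per cell. With shares in captures 1 to 3 alone r was −0.86, −0.42 and −0.62, none of which passed. SNA-I against ST6GAL1 had r 0.31 in human and 0.26 in mouse, and AAL against the sum of fucosyltransferases 0.30 and −0.24. With lectin UMIs per cell SNA-I had 0.295 and −0.57 and AAL 0.83 and 0.68, so that both mouse values turned, and none passed.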

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

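The tests without the Psca-led mouse clusters and with AAL left out of the total were chosen only after the result was seen. 11 differences between the species passed a test of the difference itself, and the values are human minus mouse on the log2 scale. Against the other classes, the share in conjunctival-like cells differed for AAL (1.15), MAA-I (−2.62), SNA-I (−1.06) and ConA (−2.03), that in corneal-like cells for WGA (1.21), that in endothelial-like cells for WGA (−1.73) and that in stromal-like cells for MPA (1.10). Between conjunctival-like and corneal-like cells the change in share differed for MPA (−0.99), AAL (1.04), MAA-I (−1.92) and ConA (−1.84). The real grouping of the 6 captures by species gave 7 differences by class and the highest of the other splits gave 0, but the real grouping is 1 of only 10 splits, too few to weigh chance.

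MAA-I and ConA took a lower share in human conjunctival-like cells than in the other human classes and a higher one in mouse. The smaller of both human minus mouse differences was −2.16 (SE 0.31) without the conjunctiva-only capture, −1.78 (SE 0.36) without the Psca-led mouse clusters, candidates for superficial cells, and −1.67 (SE 0.26) with capped cells, which argues against that capture, those clusters or a few cells with very high counts as the whole cause. With AAL left out of the total it was −0.99 (SE 0.31, adjusted p = 0.0246 by edgeR), so AAL's large share of the human total was not the whole cause of the species difference either. For the human side alone it may be, since with AAL left out the human values rose from −1.11 to −0.31 (SE 0.29) for MAA-I and from −0.87 to −0.05 (SE 0.18) for ConA, both within 2 standard errors of 0. Dissociation and capture differ along with the species, the make-up of the classes can too, and none of these can be told apart from it. Free lectin was not measured, and a biological difference of the species stays open and untested.

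The cells of 6 unnamed clusters entered no comparison and still carried lectin tags, which is why they are listed. The human cluster led by PLCG2 held 3706 lectin UMIs per cell, the one led by AC005062.1 held 6496 and the one led by CCL4 held 3562. The mouse cluster led by Krt12 held 6181, the one led by Pclaf 4045 and the one led by Slurp1 45035. The PLCG2-led, AC005062.1-led and Krt12-led clusters had low RNA counts for their captures, the CCL4-led and Pclaf-led clusters had more leading markers of another class, and the Slurp1-led cluster had RNA counts 6.53 times those of its captures. In human captures 1 to 3 the PLCG2-led cells made up 8.59%, 4.25% and 8.44%, the AC005062.1-led cells 2.39%, 6.97% and 2.71%, and the CCL4-led cells 0.499%, 0.236% and 0.604%. In mouse captures 1 and 2 and the conjunctiva-only capture the Krt12-led cells made up 7.53%, 15.1% and 5.44%, the Pclaf-led cells 3.58%, 4.14% and 1.67%, and the Slurp1-led cells 3.03%, 3.83% and 1.53%.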

How the results depend on the processing

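The alternatives with AAL left out of the lectin total, with RNA UMIs as the size of the amount fit, without the corneal-like sum of the conjunctiva-only capture, all those of the goblet-like comparisons, and the fits without the block of the amounts between 2 classes, of the species differences for conjunctival-like minus corneal-like cells, of the corneal-like clusters and of the leading genes of each class were chosen after seeing the data. Values of single lectins and genes were compared under all alternatives. Of these, 2150 kept their side of the threshold, 389 lost the call, 39 gained it and 30 turned. The 30 cover only values with a call in the main or the alternative setting. Values with no call in either setting were counted among the 2150 even where their direction changed. The mouse SNA-I and AAL correlations with lectin UMIs per cell are examples. Where a change is given below the cause was not tested, except that fewer captures or cells leave fewer sums and that a centred log ratio is by construction not an amount per cell. The human conjunctival-like against corneal-like genes, 44 up and 33 down, numbered 36 to 57 up and 27 to 40 down in the settings other than the block and left-out captures.

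Without the capture block the calls were 15 for human shares (25 with it), 6 for human amounts (26), 2 for mouse shares (6), 0 for the mouse conjunctival-like minus corneal-like shares (3; 1 at an unadjusted p below 0.05 by edgeR) and 3 for the species differences (7). The genes were 19 up and 21 down in human (44 and 33), 8 up and 4 down in mouse (27 and 16), and 0 down in goblet-like cells (11; 11 at an unadjusted p below 0.05). Besides these counts the block decided the call of SNA-I in the human conjunctival-like minus corneal-like shares and of 10 human, 11 mouse and 13 goblet-like named genes. Among the added fits it decided the calls of AAL per cell in human conjunctival-like against corneal-like cells, of 4 goblet-like amounts, of the species difference of MPA, of SNA-I between corneal-like clusters and of 3 mouse leading genes. No value that passed with the block turned without it.

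With single captures left out, the calls ranged from 3 to 20 for human shares, 6 to 26 for human amounts, 2 to 6 for mouse shares, 7 to 25 for mouse amounts, 0 to 6 for the human and 0 to 1 for the mouse conjunctival-like minus corneal-like shares, 3 to 5 for goblet-like shares and 5 to 11 for the species differences. Genes ranged from 21 to 33 up and 23 to 27 down in human, 1 to 33 up and 0 to 23 down in mouse, and 3 to 32 up and 0 to 10 down in goblet-like cells. MPA per melanocyte-like cell ranged from −0.70 to 0.0578, the latter without human capture 3.

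With limma on centred log ratios the calls were 44 for human shares, 44 for human amounts, 11 for mouse shares, 7 for goblet-like shares and 16 for the species differences. There ECA turned to 0.0268 in human conjunctival-like shares, WGA to 0.67 in the human conjunctival-like minus corneal-like shares and ConA to −0.50 in goblet-like shares. Among amounts, goblet-like cells turned for ECA (−1.41), AAL (−1.28), MAA-I (−0.33), SNA-I (−0.68), ConA (−0.97) and DSA (−1.83), limbal/basal-like cells for AAL (0.20) and DSA (0.20), melanocyte-like cells for ECA (0.17), AAL (0.20) and DSA (0.45), and mouse conjunctival-like cells for PNA (−0.31), ECA (−0.18), AAL (−0.34), DSA (−0.50) and WGA (−0.0410).

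Sums of at least 50 cells gave 10 human shares, 15 human amounts, 2 mouse shares and 1 mouse conjunctival-like minus corneal-like share, and no goblet-like value, since only 1 capture then held such cells. Capped cells gave 14 mouse amounts, 1 share in that mouse contrast, 7 goblet-like shares and 13 species differences. AAL left out gave 0 shares in the human contrast (1 at an unadjusted p below 0.05 by edgeR) and turned ECA (0.37) and DSA (0.0507) in human conjunctival-like cells. RNA UMIs as the size gave 42 human amounts and turned MPA (0.21), ECA (0.32), AAL (0.22) and DSA (0.40) in melanocyte-like and DSA (−0.21) in mouse conjunctival-like cells. The mouse contrast had 0 shares by edgeR with finer clusters, without integration, with stricter cell filters and without the corneal-like sum of the conjunctiva-only capture (0, 1, 2 and 2 at an unadjusted p below 0.05), and 4 with limma.

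Without integration 10 mouse shares and 25 mouse amounts passed, and 11 mouse genes rose. Finer clusters gave 27 mouse genes down, stricter filters 25, doublets kept 43 up and 37 down, and library totals without TMM 26 down. For goblet-like cells the genes down were 7 with DESeq2, 3 without TMM and 29 without the count filter. MPA in stromal-like shares turned to −0.0380 with stricter filters, and with doublets kept FUT8 turned to 1.07 and mouse Mgat5 to −1.43. In human, doublets kept gave 11.7% corneal-like, 16.2% limbal/basal-like, 0.395% endothelial-like and 11.3% unnamed cells, and finer clusters 9.65% limbal/basal-like, 0.687% stromal-like and 20.1% unnamed cells.

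None of the 18 lectin and gene correlations passed with lectin UMIs per cell or within any single capture. Depth limits the rarest sums. The goblet-like sum of human capture 3 rests on 30 cells and 337807 RNA UMIs, and ST3GAL6, FUT1 and FUT11 had 4, 6 and 12 UMIs in goblet-like cells, and did not pass, while GCNT1 passed with 17 UMIs.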

Other observations

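The AAL test per cell, the tests of RNA per cell and of WGA in single captures, and the fits of both without the block were chosen only after the result was seen. In means over captures with at least 20 of their cells, a pair of Psca-led mouse clusters carried the most lectin per cell of the named clusters. Cluster 9 of the conjunctival-like cells held 26233 lectin UMIs per cell, with ConA at 25% and MAA-I at 4.25%, and cluster 16 of the corneal-like cells held 20663 UMIs, with ConA at 23.8% and MPA at 6.75%. The Krt4-led conjunctival-like cluster held 18675 UMIs, and the goblet-like cells of the conjunctiva-only capture 15366. The 15 goblet-like cells of mouse capture 1, too few for these means, held 44588 UMIs per cell. These mouse means rest on different captures, so their order can also follow the captures. Cluster 16 had 1 cell in the conjunctiva-only capture, and the goblet-like mean comes from that capture alone. In human, goblet-like cells held 15279 lectin UMIs per cell, the conjunctival-like cluster led by the interferon-induced IFIT2, with SAA1 and SAA2 also leading, 12191, with AAL at 68.0% and WGA at 7.02%, the smaller of the PIGR-led clusters 10303, the CEACAM7-led 9865, the KRT6A-led 8119 and the larger PIGR-led 7353. The clusters were not tested against each other.

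Endothelial-like cells had DSA at 11.9% ± 1.79 in human and 19.0% ± 3.88 in mouse and ECA at 5.72% ± 1.51 and 14.2% ± 0.244, each above the mean of the other classes of its species, and these 4 calls ended without the block (DSA 0.45 and 0.73, ECA 0.40 and 0.87). WGA differed between the species there (−1.35 in human and 0.38 in mouse, adjusted p = 0.00332), and MPA at −0.66 and 0.29 did not pass (adjusted p = 0.0553). Human stromal-like cells carried 4.02% ± 0.931 MPA, second to goblet-like cells. Mouse keratocyte-led stromal cells (Dcn, Kera and Lum; 147 and 306 cells in mouse captures 1 and 2, 0 in the conjunctiva-only capture) had AAL at 36.2% and MPA at 3.25% in mouse capture 1, and the Col3a1-led stromal cells 36.1% and 6.46% there, the only capture with at least 20 cells of both.

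AAL took a higher share in human conjunctival-like than in corneal-like cells (log2 0.71, SE 0.23). The difference was 0.74 (SE 0.21) with capped cells, which argues against a few cells with very high counts, 1.58 (SE 0.34) in AAL UMIs per cell (no longer called without the block, 1.61), which argues against a fall of the other lectins alone, and 1.46 (SE 0.35) in AAL UMIs per RNA UMI, which argues against more RNA per cell as the whole cause of the higher amount. AAL did not pass without capture 1 (0.58) or capture 2 (0.71). Whether these cells carry more fucose was not tested and stays open. FUT2, FUT3, FUT6 and GMDS rose in them, but 8 of the 14 fucosylation genes did not pass, FUT3 lost its call without the block (0.90) and without capture 2 (0.77), and AAL against the sum of fucosyltransferases across classes had r 0.30 (adjusted p = 0.937). With AAL UMIs per cell r was 0.83 (exact p = 0.0264, adjusted p = 0.238 over the 9 human pairs alone) and −0.32 without conjunctival-like and goblet-like cells. With shares in captures 1 to 3 alone r was 0.41, 0.81 and 0.00374, none of which passed. Free lectin, and how tightly AAL binds in each cell type, were not measured and stay open.

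Within human corneal-like cells, WGA stood higher in the KRT24-led than in the CXCL14-led cluster, a pattern chosen after its values were seen (log2 2.46, SE 0.33, adjusted p = 4.50e-08 by edgeR), with DSA at 0.63 (adjusted p = 0.0116) and SNA-I at −1.11 (adjusted p = 0.00314; call ended without the block, −1.10). The WGA difference was 2.47 (SE 0.30) with capped cells, which argues against a few cells with very high counts. RNA UMIs per cell were lower in the KRT24-led cluster (mean log2 difference −0.27, SE 0.10, n = 3), by −0.43, −0.30 and −0.08 in captures 1 to 3. More RNA per cell was thus not seen there. A share of lectin UMIs need not follow RNA per cell, so this cannot decide the cause. The WGA difference was above 0 in 3 of 3 captures, which argues against 1 capture alone. CXCL14 is a limbal epithelial marker in the fixed list, and COL17A1 was a leading gene of both the CXCL14-led cluster and the limbal/basal-like cells. The corneal markers KRT12, KRT3 and ALDH3A1 led in the CXCL14-led cluster too. Whether limbal or basal cells in that cluster account for the difference was not tested. No biological explanation was tested, and free lectin, cell size and the position of the clusters in the tissue were not measured.

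Class names were permuted within captures 100 times, the real names included. For human shares the real count was 25 and the highest other 4, for human amounts 26 and 9, and for mouse shares 6 and 5. In each, 1 permutation of 100 was as high, the real one, which argues against chance for the count of calls as a whole. Single calls are not weighed by this, and the mouse share counts lay close together. For mouse amounts 12 of 100 permutations gave as many calls, with 9 for the real names and 14 for the highest other, so chance cannot be excluded. For the list genes of conjunctival-like against corneal-like cells the 10 splits of 6 sums are too few, with 77 calls against a highest other of 0 in human and 43 against 0 in mouse.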
